A study of Arabidopsis thaliana with 11 samples.

How the data were processed

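Nuclei of A. thaliana seedlings grown for 7 to 10 days in liquid medium were treated with micrococcal nuclease and CENH3 complexes were precipitated, per the labels' protocols. The series has 11 samples. The 6 ChIP libraries with peak lists were grouped by CENH3 variant from their titles, 2 per variant. The 3 antibody controls and 2 input samples are not analysed here.

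BWA, MACS2 and the genome build TAIR10 are named per the submitters' processing notes. Peaks were called for each library on its own with MACS 2.1.0.20140616, per the file headers, with no fragment model, tags extended to 165 bp, all duplicate tags kept, the larger library scaled down to the smaller and a q-value cutoff of 0.05. The 2 lists of a variant used the same control alignment, per the file headers, and the headers do not say which sample that was, so 3 controls served the 6 lists. The effective genome size was set to 2.7 Gb, per the file headers, far above the size of this genome. That setting lowers the genome-wide background that MACS uses as a minimum, so a place where the control has hardly any reads can be called on few ChIP tags. The deposited pile-up is the coverage of extended ChIP tags at the summit after scaling, the deposited −log10 p-value and −log10 q-value are those of the peak caller, and the deposited fold enrichment is the ratio of ChIP to local background at the summit. That ratio was read as (pile-up + 1) / (background + 1), the usual definition of this peak caller. Lengths and positions are as the authors deposited them, 1-based. All duplicate tags count in the pile-up, and how tags that match several places were treated is not given in the sources used here.

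Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Only chromosomes 1 to 5 entered comparisons. The control background of a peak was solved from that ratio, and its lowest possible value computed as the scaled tag total times the extension over the genome size setting. Depth was the tag total of the headers. Since lists hold only peaks past the authors' cutoff, a region without a peak may still have had signal, and depth and control both set what was called. No sequence of the genome was used here, so the planned satellite share and the satellite-defined centromere interval were replaced or left out. The interval was the planned fallback, the 3 Mb window with the most AtCENH3 peak bases, found in steps of 10 kb.

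Covered length and window share were compared between variants by exact two-sided permutation. Agreement was the Jaccard index of covered bases over all 15 pairs of libraries, tested over the 15 ways to pair the libraries. The midpoint was the median position of peak bases in the window, tested in the same way. The overlap of bases called in both replicates was set against 10000 rotations (seed 20) within the span of peaks in the window. Variant-specific regions were merged regions with a peak in both replicates of a variant and in no other library, with an overlap of 1 bp counting. The block on chromosome 4 was noticed in the data and defined as the longest stretch of LoCENH3 peaks, joined over 10 kb, without a peak of another variant, and groups of peaks were joined over 200 kb for description. The functions were tested before use, and on simulated intervals 0 of 200 trials differed from a direct count. Of 100 random rotations of the AtCENH3 replicate 1 peaks, set against those peaks, 6 gave a rotation p under 0.05. A rate near 0.05 was built into that check. It does not cover unrelated sets that gather in the same part of the span. Of 20 sets made from a part of those peaks, slightly moved, 20 gave a p under 0.05.

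Genes came from a RefSeq gene table of assembly TAIR10.1, with 37899 genes on the nuclear chromosomes. Its nuclear chromosomes were assumed to have the numbering of TAIR10, and no coordinate of that table is printed. The 5 fixed gene lists and the list of genes in the windows were tested by Fisher's exact test with Benjamini-Hochberg adjustment over lists and variants. Genes were named by a rule set before the data were examined: of genes with a peak in both replicates of a variant, the first 25 by number of libraries and then by mean bases under peaks, up to 5 per variant found in that variant alone, and list members with a peak. Named regions were the 3 highest peaks of each list, the 5 longest specific regions of each variant and up to 10 regions outside the windows in both replicates of a variant, with the HTR12 peaks added as list members. The sole LoCENH3 region outside the block was named after its count was seen.

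Alternatives were the better-scoring part of each list by −log10 q, lists of equal length, leaving out each library, 10 kb bins, a reciprocal overlap of 50%, peaks or regions joined over 1000 bp, rotation over whole chromosomes, windows widened by 1 or 2 Mb, other midpoints, 50% coverage of a region or gene, and the replicate number as a block. The better-scoring part held 50% of the peaks of each list, such as 158 of 315 in AtCENH3 replicate 1. Leaving out the chromosome 4 block was added after seeing the data.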

Results

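CENH3 is the histone H3 variant that replaces H3 in the nucleosomes of centromeres. The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from Arabidopsis thaliana seedlings in which CENH3 came from 3 species: AtCENH3, the plant's own protein, in wild-type Columbia; LoCENH3, from Lepidium oleraceum, in the cenh3-1 mutant; and ZmCENH3, from maize, in the same mutant. Each protein was precipitated with an antibody against that protein from nuclei digested with micrococcal nuclease. Each variant had 2 libraries, replicates 1 and 2, and the labels do not say whether these came from separate cultures. The permutation p-values over libraries therefore measure only the spread between these samples, which may be technical. The rotation and Fisher's exact tests take positions and genes as units and do not measure that spread. The ChIP libraries held 9016364 and 13280742 tags for AtCENH3, 22489151 and 23205886 for LoCENH3, and 13886693 and 15798998 for ZmCENH3. Their controls held 9239707, 12730185 and 9825449 tags, and the 2 lists of a variant shared 1 control. The question was whether the centromeres kept their places when the CENH3 protein differed.

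Peaks of all 3 variants clustered in a limited part of each chromosome, and ZmCENH3 covered the most sequence. ZmCENH3 peaks numbered 404.5 ± 4.95 per library and covered 189.7 ± 8.68 kb, against 285 ± 42.4 peaks and 120.4 ± 13.8 kb for AtCENH3 and 294 and 308 peaks and 135 ± 6.78 kb for LoCENH3 (mean ± SD, n = 2 each, chromosomes 1 to 5). Mean peak length was 423 ± 14.5 bp for AtCENH3, 449 ± 7.76 bp for LoCENH3 and 469 ± 15.7 bp for ZmCENH3. Of the LoCENH3 length, 75.7 kb in replicate 1 and 60.5 kb in replicate 2 lay in a single block on chromosome 4 that held no peak of the other variants, described further on. Outside that block LoCENH3 covered 67.2 ± 17.5 kb in 175.5 ± 29.0 peaks, less than either AtCENH3 library, although its libraries were the deepest. The log2 ratio of covered length was 0.66 ± 0.18 (SD) for ZmCENH3 over AtCENH3, 0.49 ± 0.10 for ZmCENH3 over LoCENH3 and 0.17 ± 0.18 for LoCENH3 over AtCENH3. The last became -0.84 ± 0.42 without the block, and ZmCENH3 over LoCENH3 became 1.496 ± 0.39. With lists cut to equal numbers of peaks ZmCENH3 over AtCENH3 was 0.32. The ranges of the libraries did not overlap in any of the 3 comparisons, but the exact two-sided permutation p was 0.333 in each, the smallest that 2 libraries against 2 can give.

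Chromosome 5 carried the most peak bases in AtCENH3 and ZmCENH3. AtCENH3 covered 47.1 ± 4.02 kb there, LoCENH3 23.6 ± 9.22 kb and ZmCENH3 85.9 ± 5.82 kb. Most of this lay between 11.59 and 12.17 Mb, where AtCENH3 covered 40.0 ± 3.37 kb, LoCENH3 20.9 ± 8.22 kb and ZmCENH3 75.1 ± 5.33 kb. On chromosome 3, ZmCENH3 covered 14.4 ± 2.04 kb between 13.57 and 14.15 Mb, against 6.14 ± 1.45 kb for AtCENH3 and 4.51 ± 0.00707 kb for LoCENH3. On chromosome 4 between 3.73 and 4.03 Mb the lengths were 28.0 ± 0.972 kb for ZmCENH3, 18.7 ± 0.738 kb for AtCENH3 and 11.4 ± 3.23 kb for LoCENH3. The variants were closer on chromosome 2 between 3.10 and 3.72 Mb, with 12.1 ± 0.0856, 11.1 ± 0.600 and 8.32 ± 0.625 kb for ZmCENH3, AtCENH3 and LoCENH3. Chromosome 1 had 2 main groups of peaks. Between 14.51 and 15.49 Mb ZmCENH3 covered 15.3 ± 0.549 kb, AtCENH3 10.9 ± 4.40 kb and LoCENH3 5.25 ± 1.41 kb. In a narrow stretch from 16.51 to 16.53 Mb, AtCENH3 and ZmCENH3 covered nearly equal lengths, 13.3 ± 0.156 and 13.4 ± 0.163 kb, and LoCENH3 covered 9.29 ± 1.92 kb.

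**Figure D1:**
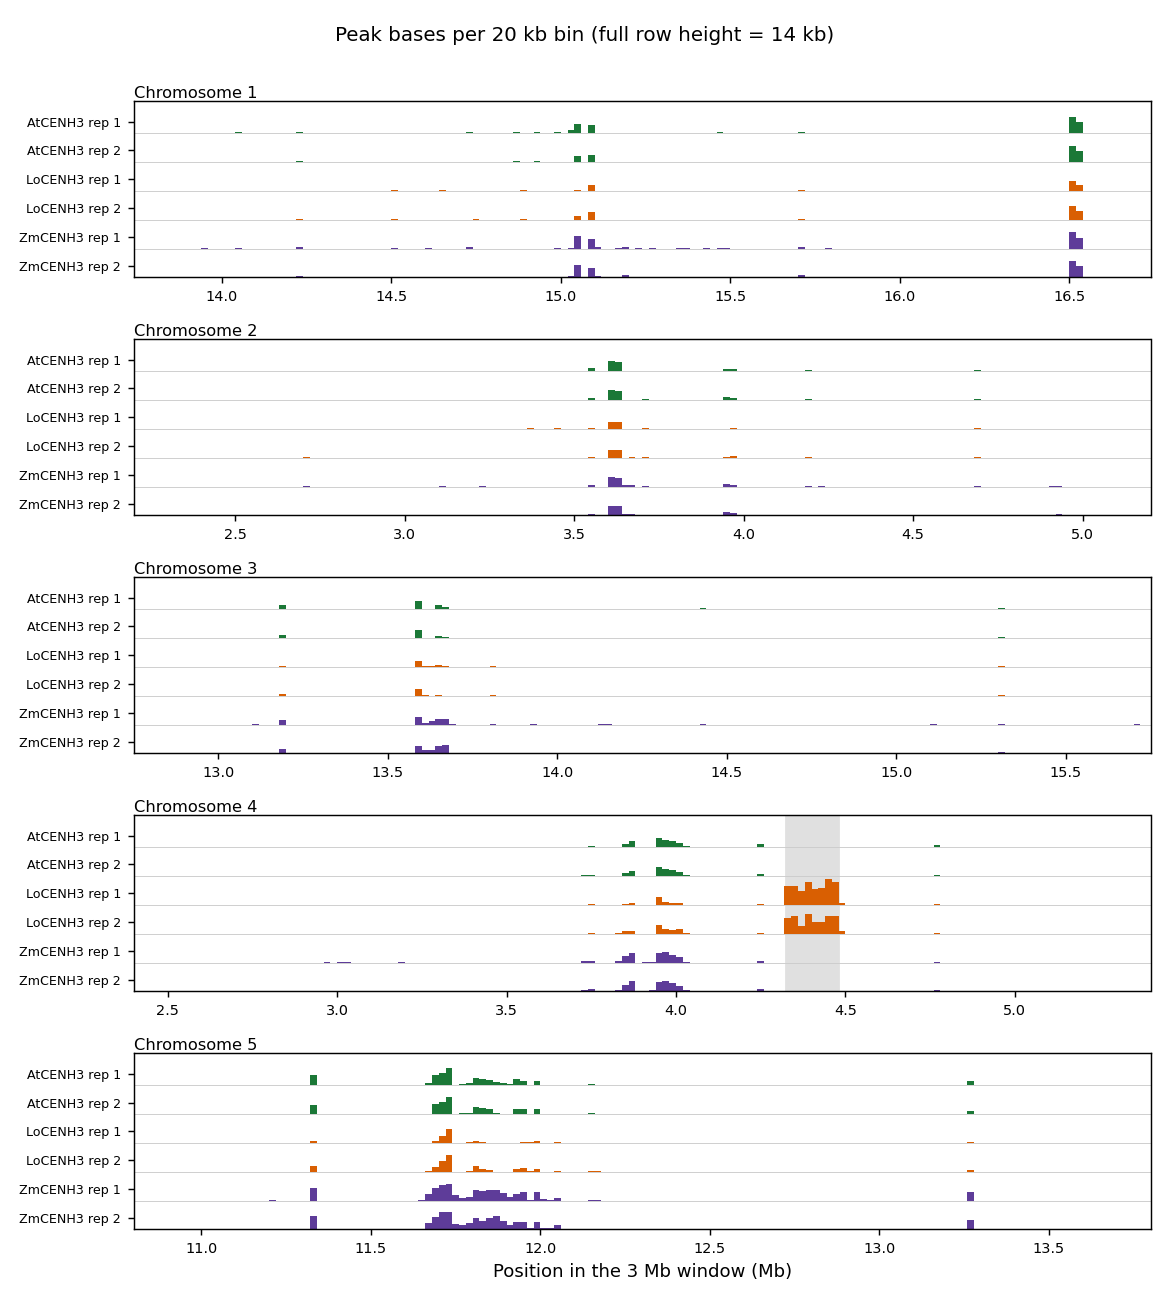
Peak bases in 20 kb bins along the 3 Mb window of each chromosome (horizontal axis, Mb), with 1 row per library coloured by variant and bar height giving covered bases; the grey band on chromosome 4 marks the block from 4.33 to 4.48 Mb. The main groups of bars stand at the same positions in all 6 libraries, and the LoCENH3 rows alone fill the block.

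Nearly all peak bases lay near the centromeres in every line. In the absence of a genome sequence, the centromere interval was taken as the 3 Mb of each chromosome with the most AtCENH3 peak bases: 13.74 to 16.74 Mb on chromosome 1, 2.2 to 5.2 Mb on chromosome 2, 12.75 to 15.75 Mb on chromosome 3, 2.4 to 5.4 Mb on chromosome 4 and 10.8 to 13.8 Mb on chromosome 5. These windows make up 12.6% of the span up to the last annotated gene of each chromosome. They held 96.2% ± 0.157 of AtCENH3 peak bases, 98.7% ± 0.261 of LoCENH3 bases and 95.2% ± 0.282 of ZmCENH3 bases (SD, n = 2 each). The AtCENH3 value follows in part from the way the windows were set, which used those lists. LoCENH3 exceeded AtCENH3 by 2.48 percentage points, more than the spread between replicates, but without the chromosome 4 block its share was 97.2% ± 1.12, within 1 SD of AtCENH3. Each comparison gave an exact permutation p of 0.333, the smallest possible.

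Outside the chromosome 4 block the bases of the 3 variants were largely nested. Of the bases called in both AtCENH3 replicates near the centromeres, 93.0% were also called in both ZmCENH3 replicates, and 59.5% of the ZmCENH3 bases were called in AtCENH3. Of all LoCENH3 bases, 53.1% were shared with AtCENH3 and 55.2% with ZmCENH3, and of those outside the block 94.5% and 98.0%, while LoCENH3 took up 47.8% of the AtCENH3 bases and 31.7% of the ZmCENH3 bases. The shared length was 91.6 kb for AtCENH3 and ZmCENH3, 47.1 kb for AtCENH3 and LoCENH3 and 48.9 kb for LoCENH3 and ZmCENH3. Rotating the peaks of a variant at random within the span of peaks near each centromere gave 1.99, 0.968 and 1.48 kb on average, so that the observed overlaps were 45.9, 48.6 and 33.0 times the random value with the block included. Without it the last 2 were 83.1 and 53.5 times. This rise, like that of the LoCENH3 shares to 94.5% and 98.0%, follows from the definition of the block, which holds no peak of another variant. None of 10000 rotations reached the observed overlap for any pair (one-sided permutation p = 1e-04, the smallest they can give). Rotations move peaks onto any sequence of the span, and how tags of repeated sequence were placed is not known here. The result therefore cannot tell shared binding from tags piling up on the same sequence. It does not by itself show that centromeres kept their places. The nesting held on each chromosome, here outside the block and over whole chromosomes rather than only near the centromeres. The share of LoCENH3 bases called in ZmCENH3 ran from 89.2% on chromosome 3 to 99.6% on chromosome 2. For AtCENH3 bases called in ZmCENH3 it ran from 82.8% on chromosome 2, with the peaks near its start included, to 94.0% on chromosome 5. Among regions merged over all lists, 102 had a peak in all 6 libraries and 100 of these lay in the windows: 34 of the 102 were on chromosome 5, 27 on chromosome 4, 18 on chromosome 2, 15 on chromosome 1 and 8 on chromosome 3.

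Libraries of the same variant shared more bases than libraries of different variants. The Jaccard index, shared bases over bases in either list, was 0.725 for the AtCENH3 replicates, 0.741 for ZmCENH3 and 0.491 for LoCENH3. Between variants it averaged 0.509 for AtCENH3 and ZmCENH3 (0.478 to 0.536 over 4 pairs of libraries), 0.315 for AtCENH3 and LoCENH3 (0.233 to 0.401) and 0.246 for LoCENH3 and ZmCENH3 (0.184 to 0.310). The mean within variants, 0.652, exceeded the mean between variants, 0.356, by 0.296. The true pairing ranked first of the 15 ways to pair 6 libraries (exact permutation p = 0.0667, one-sided, the smallest this design allows). The excess includes any effect of the control that replicates shared. The LoCENH3 replicates overlapped each other less than 3 of the 4 pairs of AtCENH3 and ZmCENH3 libraries did, but more than all 4 without the block. Without it LoCENH3 replicate 2 overlapped AtCENH3 replicate 2 (0.606) about as much as its own replicate (0.598).

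**Figure D2:**
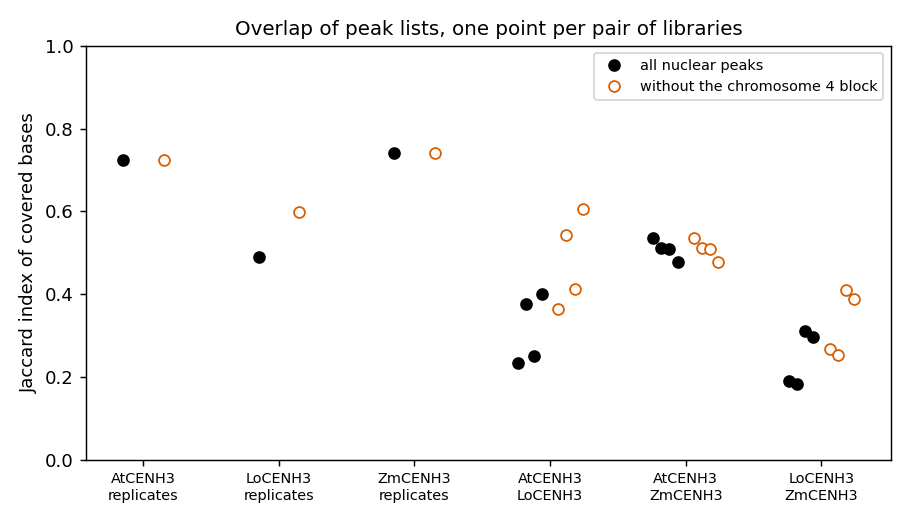
Jaccard index of covered bases (vertical axis, 0 to 1) for each of the 15 pairs of libraries, grouped by the variants compared; filled points use all nuclear peaks and open points leave out the chromosome 4 block. Leaving out the block raised the LoCENH3 replicate pair from 0.491 to 0.598 and left pairs of AtCENH3 and ZmCENH3 where they were.

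The median position of the peak bases stayed within a few kb on chromosome 2 and moved further in ZmCENH3 on chromosomes 3 and 5, but other measures of the middle disagreed. Relative to AtCENH3, the median position of ZmCENH3 peak bases lay 83.7 kb further along chromosome 5, where replicates of a variant differed by at most 2.45 kb, and 41.0 kb further along chromosome 3, where the ZmCENH3 replicates differed by 16.9 kb. LoCENH3 differed from AtCENH3 by 3.88 kb on chromosome 5 and by 0.384 kb on chromosome 3. On chromosome 2 the shifts were 1.01 kb for LoCENH3 and 1.77 kb for ZmCENH3. By the fold-weighted mean position ZmCENH3 lay 46.7 kb further than AtCENH3 on chromosome 5 and 9.77 kb further on chromosome 2, but 17.1 kb in the other direction on chromosome 3, where the ZmCENH3 replicates differed by 13.1 kb. By the midpoint between the outermost peaks it lay 51.9 kb in the other direction on chromosome 5, 119 kb further on chromosome 2 and 61.5 kb further on chromosome 3, where the replicates differed by 205 kb. On chromosome 4 the LoCENH3 median stood 425 kb from that of AtCENH3 with the block and 11.1 kb without it, next to 11.7 kb for ZmCENH3. On chromosome 1 the AtCENH3 replicates themselves differed by 1321 kb, since the median fell in either of the 2 main groups of peaks. Over the chromosomes the mean distance between libraries was 245 kb between variants and 99.8 kb within them. Chromosome 1 dominates both means. Replicates differed there by 1321 kb in AtCENH3 and 139 kb in ZmCENH3, and by at most 16.9 kb on any other chromosome. The LoCENH3 and ZmCENH3 medians stood 661 and 556 kb from that of AtCENH3 on chromosome 1. The pooled values below therefore do not show a shift on every chromosome. The excess of 145 kb had an exact permutation p of 0.133 (one-sided) and was 89.2 kb (exact p = 0.267) without the block. The excess rose to 251 and 261 kb without AtCENH3 replicate 1 or 2, which took the 1321 kb out of the distances within variants. Without LoCENH3 replicate 1 or 2 it was 74.7 and 76.2 kb. In the better-scoring part of each list it was 4.69 kb (exact permutation p = 0.0667).

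LoCENH3 alone had a dense block of peaks on chromosome 4, from 4325454 to 4482371 (TAIR10, 157 kb). Replicate 1 had 139 peaks there, covering 48.2% of the block, and replicate 2 had 112 peaks covering 38.5%. Together these made up 47.3% and 36.4% of the 2 lists, while AtCENH3 and ZmCENH3 had 0 peaks in the block, as its definition requires: the longest stretch of LoCENH3 peaks, joined over 10 kb, that meets no peak of another variant. The edges of the block differed by 1429 bp and 841 bp between replicates, and the Jaccard index of the called bases inside it was 0.398. Peaks in the block were low: the median ChIP pile-up at the summit was 13.6 tags in replicate 1 and 10.97 in replicate 2, against 243 and 167 at the other LoCENH3 peaks. The control background implied by the authors' fold enrichment equalled the genome-wide minimum of 0.778 tags, to within 0.02, at 82.7% of block peaks in replicate 1 and 79.5% in replicate 2, and at 0 of the 155 and 196 other peaks. The block contains 41 annotated genes, of which 36 are labelled pseudogenes.

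**Figure D3:**
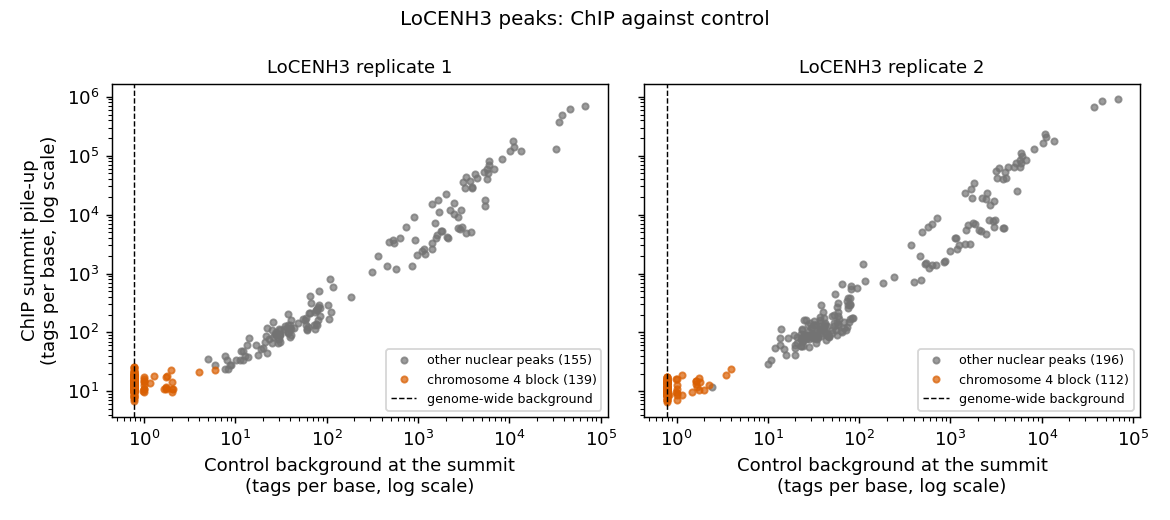
ChIP pile-up at the summit (vertical axis, tags per base, log scale) against the control background at the same summit (horizontal axis, log scale) for every nuclear LoCENH3 peak, 1 panel per replicate; the dashed line is the genome-wide background of 0.778. Peaks of the chromosome 4 block, in orange, lie on that line in 82.7% of cases in replicate 1 and 79.5% in replicate 2, the others reaching a background of about 6 and 4 tags, and have pile-ups of 6.79 to 26.0 and 6.58 to 23.6.

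Regions called in both replicates of a single variant and in no other library numbered 95 for ZmCENH3, 77 for LoCENH3 and 12 for AtCENH3. Of the 77 LoCENH3 regions 76 were in the chromosome 4 block, leaving 1, at 14887767 to 14888028 on chromosome 1. The longest ZmCENH3 regions were on chromosome 5 at 11753969 to 11756413, 11859667 to 11861234, 11891373 to 11892773 and 11716634 to 11717769, among the main group of peaks of that chromosome, and on chromosome 1 at 142222 to 143693. The AtCENH3 regions were short. Their longest were 500 bp at 14935670 to 14936169 on chromosome 1, 415 bp at 11863637 to 11864051 on chromosome 5 and 387 bp at 14873454 to 14873840 on chromosome 1, followed by 10251454 to 10251754 on chromosome 5 and 28553 to 28813 on chromosome 2. In the block the longest LoCENH3 regions were 4396269 to 4399586, 4400865 to 4403966, 4342741 to 4345219, 4357911 to 4360388 and 4333814 to 4336240. The total of 184 regions exceeded that of each of the other 14 pairings of the libraries, the highest of which gave 97 (exact permutation p = 0.0667, one-sided). Like the Jaccard excess, this includes any effect of the control that replicates shared. It does not by itself show binding particular to a variant. Without the block the total was 108. With 1 library in a variant, which then needed no second call, AtCENH3 had 20 regions without its replicate 1 and 49 without its replicate 2, LoCENH3 116 and 152, and ZmCENH3 156 and 140. Joining regions over 1000 bp left 7 for AtCENH3, 10 for LoCENH3 and 48 for ZmCENH3. Equal list lengths left 29 ZmCENH3 regions, fewer than the 56 of LoCENH3, and 15 for AtCENH3, and the better-scoring part of each list left 33 for ZmCENH3, 3 for LoCENH3 and 4 for AtCENH3.

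Genes under the peaks were mostly labelled pseudogenes in the gene table. That label was taken as given, and the kind of sequence that carries it was not examined. In the gene table used, 112 genes overlapped a peak in both replicates of at least 1 variant: 45 for AtCENH3, 54 for LoCENH3 (20 without the block) and 74 for ZmCENH3. Pseudogenes made up 41 of the 45, 47 of the 54 and 66 of the 74. The 20 genes with a peak in all 6 libraries included 3 protein-coding genes, AT2G08986, AT1G40104 and AT2G07981. In AT2G08986, 5740.5 ± 14.8 bp lay under peaks in AtCENH3, 4239.5 ± 433 bp in LoCENH3 and 5643 ± 36.8 bp in ZmCENH3 (mean ± SD, n = 2 each). In AT1G40104 the lengths were 3475.5 ± 119.5, 3001 ± 629 and 3833 ± 0 bp, and in AT2G07981 they were 1076.5 ± 20.5, 764 ± 35.4 and 910 ± 90.5 bp. A run of neighbouring pseudogenes on chromosome 1, AT1G43740, AT1G43745, AT1G43750 and AT1G43755, had peaks in every library, and in AT1G43745 these covered 2434.5 ± 2.12 bp in AtCENH3, 2032 ± 226 bp in LoCENH3 and 2423.5 ± 13.4 bp in ZmCENH3. The other pseudogenes with peaks in all libraries were AT5G32125, AT5G31804, AT5G31736, AT5G31999, AT5G31753 and AT5G32161 on chromosome 5, AT4G06714, AT4G07456, AT4G06666 and AT4G06700 on chromosome 4, AT3G43356 and AT3G33080 on chromosome 3 and AT2G07789 on chromosome 2. AT5G31804 had 1737 ± 324 bp under ZmCENH3 peaks against 406.5 ± 50.2 bp for AtCENH3 and 193.5 ± 6.36 bp for LoCENH3. AT4G06666 had 605 ± 82.0 bp against 113 ± 14.1 and 99 ± 8.49 bp. AT5G29975, AT1G40095, AT5G32293, AT5G32306 and AT5G31719 had peaks in 5 libraries, and in each of these genes the LoCENH3 mean was the lowest of the 3 variants, for instance 372 ± 526 bp in AT5G29975 against 2384.5 ± 275 bp for AtCENH3 and 3352 ± 87.7 bp for ZmCENH3.

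Genes with peaks in a single variant were 34 for LoCENH3, all in the chromosome 4 block and led by the pseudogenes AT4G07520, AT4G07660, AT4G07680, AT4G07563 and AT4G07668. ZmCENH3 had 18, led by RCAR1 (AT1G01360), an abscisic acid receptor gene, AT5G32179, HTR12 (AT1G01370), AT4G06692 and AT5G31945. AtCENH3 had 2, AT2G01029 and AT1G40073. HTR12 is the gene of the plant's own CENH3, and it was the only member of the fixed gene lists with a peak in any library. It made 1 of 6 genes of the CENH3 and kinetochore list in ZmCENH3 (Fisher's exact test, two-sided, p = 0.0117, adjusted p = 0.0525 over 18 tests, not past 0.05). The lists of other H3 genes, ribosomal RNA genes, highly expressed photosynthesis genes and housekeeping genes had 0 of 8, 4, 8 and 6 members under peaks in each variant (Fisher's exact test, adjusted p = 1). Genes inside the windows made up 39 of the 45 AtCENH3 genes, 54 of the 54 LoCENH3 genes and 66 of the 74 ZmCENH3 genes (adjusted p at most 1.08e-33, Fisher's exact test), although genes are not independent and the windows were set on AtCENH3 peaks.

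Outside the windows there were 39 regions, of which 17 were in both replicates of a variant and 22 in a single library. In all 6 libraries a peak stood at 13180865 to 13181673 on chromosome 1, over the pseudogene AT1G35647, and at 5278678 to 5279120 on chromosome 3, between genes. Next to the latter, 5283958 to 5286650 over the pseudogene AT3G15602 was called in AtCENH3 and ZmCENH3, and 5279752 to 5280828 over AT3G15600 and 5282975 to 5283370 were called in both ZmCENH3 replicates and in some other libraries. Near the start of chromosome 2, AtCENH3 and ZmCENH3 had peaks in both replicates at 19165 to 19596 (AT2G01026) and 62689 to 63075 (AT2G01037). At 27218 to 27545 both AtCENH3 replicates and ZmCENH3 replicate 1 had a peak. No LoCENH3 library had a peak at these 3 sites. The remaining regions in 3 or 4 libraries were 12250560 to 12250983 on chromosome 3 (AT3G30695) and 10245879 to 10246146 on chromosome 5 (AT5G28263).

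At HTR12, both ZmCENH3 libraries had a peak at each end of the gene and none between. In replicate 1 they lay at 142237 to 143693 and 145500 to 145930 on chromosome 1, with authors' fold enrichments of 4.43 and 3.78, and in replicate 2 at 142222 to 143622 and 145537 to 145904, with 5.20 and 3.61. The first peak lay mostly over the neighbouring RCAR1, of which it covered 1032.5 ± 10.6 bp (SD, n = 2). Both peaks together covered 569 ± 94.8 bp of HTR12. The uncalled gap was 1806 bp in replicate 1 and 1914 bp in replicate 2. None of the 4 other lists had a peak there.

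Peak height is the authors' fold enrichment over the control and is used only within a list. Its median over all peaks of a list was 5.21 and 5.46 in the AtCENH3 lists, 6.29 and 4.85 in LoCENH3 (3.24 and 3.40 outside the block), and 4.30 and 4.28 in ZmCENH3, with maxima of 53.3, 47.2, 16.0, 21.7, 43.0 and 42.2. The median −log10 q was 17.3 and 25.3, 13.2 and 12.9, and 18.8 and 17.7. The highest peak of both AtCENH3 and both LoCENH3 lists was the same site on chromosome 5, 11732008 to 11732730 in AtCENH3 replicate 1, and it was among the top 3 of both ZmCENH3 lists. The ZmCENH3 lists were led by 3617972 to 3620129 on chromosome 2, over AT2G08986, and next by 3953425 to 3953779 on chromosome 4, a site that also ranked among the top 3 in AtCENH3. The other leading peaks were 11708109 to 11708418 on chromosome 5 in AtCENH3, 3622468 to 3622774 (in AT2G08986) and 3607043 to 3607357 on chromosome 2 in LoCENH3 replicate 2, and 4339184 to 4340238 and 4463103 to 4464189 in the chromosome 4 block in LoCENH3 replicate 1. The block peaks had pile-ups of only 26.0 and 25.5 tags, against 174622 at the first-ranked peak of that list. The rank of these block peaks rests on a control background at the genome-wide minimum of 0.778 tags. Across the 102 regions in all 6 lists the heights ranked alike, with a Spearman correlation across regions, which are not independent, of 0.946 to 0.981 between replicates, whose folds share a control. Between AtCENH3 and LoCENH3 libraries it was 0.822 to 0.865, between AtCENH3 and ZmCENH3 0.733 to 0.750, and between LoCENH3 and ZmCENH3 0.681 to 0.706. Over all regions that 2 lists shared it was lower: 0.851 to 0.921 between replicates, 0.726 to 0.842 for AtCENH3 and LoCENH3, 0.584 to 0.623 for AtCENH3 and ZmCENH3 and 0.585 to 0.656 for LoCENH3 and ZmCENH3.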

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

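LoCENH3 replicate 1 was the only list with peaks on the organelle sequences, which no comparison used. A chloroplast peak at 20770 to 21004 had a fold enrichment of 1.17 and a pile-up of 3086 tags, and a mitochondrial peak at 92092 to 92479 had a fold of 1.48 and a pile-up of 213. The other 5 lists had none. No explanation was tested.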

How the results depend on the processing

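Leaving out the chromosome 4 block was chosen after the data were seen; the other alternatives were set before the data were examined. Of 162 values under alternatives, 121 kept their direction and their side of the threshold, moved by less than the spread between replicates or, for counts, stayed within 1.5 times, and 41 moved further. Some of the 121 could not move, such as the length of ZmCENH3 over AtCENH3 without a LoCENH3 library. The midpoint excess counts among the 121 even at 4.69 kb, against 145 kb in the main setting. The overlap between variants stayed above random placement under every alternative run (permutation p = 1e-04, the smallest possible), from 5.60 times with 10 kb bins to 544 times with rotation over whole chromosomes. The latter value also counts the clustering of peaks near the centromeres. The within-variant excess of the Jaccard index stayed positive, from 0.205 to 0.371, and the midpoint excess from 4.69 to 261 kb. With 2 libraries per variant the exact permutation tests of covered length and share could not pass a threshold, and no model that pools the spread was fitted.

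With the better-scoring part of each list, log2 covered length was -0.14 for LoCENH3 over AtCENH3, which changed its sign, and 0.69 for ZmCENH3 over LoCENH3. Window shares were 99.01% for AtCENH3, 98.98% for LoCENH3 and 96.0% for ZmCENH3, specific regions 4, 3 and 33, and genes 16, 16 and 34. Shorter lists lower the gene counts by construction and can change the counts of specific regions. With equal list lengths ZmCENH3 was 0.32 over AtCENH3 and 0.21 over LoCENH3 on the log2 scale, window shares were 96.7%, 99.02% and 94.8%, and ZmCENH3 had 29 specific regions and 49 genes. Without the block, LoCENH3 over AtCENH3 was -0.84, again of the other sign, ZmCENH3 over LoCENH3 1.496, the LoCENH3 share 97.2%, its specific regions 1 and its genes 20. Windows widened by 1 Mb gave 97.4%, 99.045% and 96.1%, and by 2 Mb 97.4%, 99.1% and 96.1%. Joining regions over 1000 bp left 7, 10 and 48 specific regions for AtCENH3, LoCENH3 and ZmCENH3, by construction fewer since neighbours merge, and 50% coverage left 49 for LoCENH3. Requiring 50% of a gene left 5, 13 and 13 genes. Without one library at a time the specific regions ranged from 12 to 49 for AtCENH3, 77 to 152 for LoCENH3 and 96 to 156 for ZmCENH3, the higher values arising where a variant had 1 library and needed no second call. Other causes were not tested.

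With the replicate number as a block, the Jaccard excess was 0.295, using between-variant pairs of different number. The midpoint excess was 140.5 kb, using between-variant pairs of the same number, so the block was applied differently. Each had an exact permutation p of 0.167, the smallest that 6 pairings allow. No call was possible with or without the block, so this cannot show that a call was stable. The labels do not say what a shared number means, and same-numbered libraries had correlations of their deviations over 221 bins of -0.13, -0.14 and 0.0304. The blocked log2 covered lengths stayed within the replicate spread. The window share has the same mean with a block. The satellite share and its alternatives, the satellite-defined interval and the exclusion of assembly gaps were not run.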

Other observations

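All tests in this part were chosen after the result was seen. Each list had its highest pile-up at the same place, near 13.59 Mb on chromosome 3, where a peak from 13589846 to 13592557 in AtCENH3 replicate 1 reached 783952 tags on a single base, 8.69% of the scaled tags of that library. In the other libraries the summit held 6.95% (AtCENH3 replicate 2), 5.45% and 7.26% (LoCENH3) and 8.83% and 8.75% (ZmCENH3). The control background at the same summit was 16368 and 16774 tags in the AtCENH3 lists, 67745 in the LoCENH3 lists and 23182 in the ZmCENH3 lists. Among genes inside the windows, pseudogenes were more frequent under peaks than elsewhere: 35 of 39 against 67.9% in AtCENH3, 47 of 54 against 67.8% in LoCENH3 and 60 of 66 against 67.7% in ZmCENH3 (Fisher's exact test, two-sided, adjusted p = 0.00278, 0.00271 and 4.23e-05 over 3 tests). Of the 54 LoCENH3 genes 34 lay in the chromosome 4 block; without it 17 of 20 were pseudogenes, against 68.0% (Fisher's exact test, two-sided, p = 0.147), a difference of similar size over fewer genes. Gene length was not taken into account, and pseudogene is here only the label of the gene table.

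The chromosome 4 block may reflect the control of the LoCENH3 lists rather than LoCENH3. A control almost without reads in the block is in line with the data, since 81.3% of the 251 block peaks sat at the genome-wide background and 0 of the 351 other LoCENH3 peaks did. Whether LoCENH3 bound there as strongly as at its other peaks cannot be told apart from weaker binding, since most block peaks have hardly any control reads to compare with. The authors' median folds in the block, 7.89 and 6.42 against 3.24 and 3.40 at the other peaks, rest on that minimum and do not measure binding. The pile-ups were low: their medians were 1.67 and 1.34 times a control background taken from 8 peaks of replicate 1 outside the windows. The lower quartiles of the fold at the other LoCENH3 peaks were 2.58 and 2.46, but a fold adds 1 to both of its terms and uses the local control. The pile-up medians also lay below the 17.6 tags that an even spread of the scaled tags would give. That spread includes tags of the organelles and tags stacked at centromeric sites. These comparisons decide nothing about binding, since none has a control signal from the block itself. Why the control has so few reads there stays open, and the peak lists of the other variants cannot tell, since the block was defined to hold none of their peaks. The better-scoring part of the lists kept 29 of the 139 and 5 of the 112 block peaks.

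The ZmCENH3 peaks at both ends of HTR12 are far from any centromere. A depleted control is argued against, since its background at the 4 peaks was at least 14.999 tags, above the lower quartiles over all ZmCENH3 peaks (9.0004 and 9.40). A candidate explanation is extra copies of the flanks of HTR12, carried by the transgene that supplies maize CENH3: 0 bases were called between the end peaks. This stays open, since the sequence of the construct is not in the labels, and the LoCENH3 line, which also carries a transgene, had no peak there, which its control could hide if that control came from a line with the same flanks.

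Outside the block LoCENH3 had the fewest peaks. Fewer reads are argued against, since the smaller scaled total of its lists was 1.30 times the largest among the other lists. Whether a control richer in centromeric reads lies behind the difference from ZmCENH3 stays open: at the 102 regions in all lists the control background per scaled tag was 1.09 times that of the ZmCENH3 lists at the median and 1.73 times at the upper quartile, and regions that LoCENH3 lost are not among them. Against AtCENH3 the median ratio was 3.40, which leaves a stronger control signal open as a possible explanation of part of that difference, although ZmCENH3 had a ratio of 3.13 to AtCENH3 and more regions. A weaker precipitation of LoCENH3 or a narrower distribution of the protein also stays open, and neither was tested.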
